A study of Mus musculus with 28 samples.

How the data were processed

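Hippocampal RNA of female 3xTg-AD and WT mice was sequenced as stranded poly(A) libraries with paired reads of 100 bases on a NovaSeq, per the labels' protocols. The submitters' processing notes name STAR, Subread and featureCounts and the mouse build mm10, without versions, roles or order; the gene annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. The deposited file is a table of raw counts per gene symbol, made by the authors with 1 column per library, not normalized and not pooled. It holds 24062 genes in 28 libraries, each column was matched to its library by name, and 0 columns were left unused. Because the strand setting is not given, counts of genes that overlap another gene, and of genes with close copies, are uncertain.

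Libraries were grouped by genotype and treatment from the labels into 7 groups of 4. The labels number the libraries of each group but do not say that a number marks a shared litter, batch or day, so the number was not part of the model. They also do not say in so many words that each library is a different animal; if some are not, the p-values measure only the spread between these libraries. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom between libraries of a group was 12.8. Total counts ran from 32080861 to 54019519 per library. No batch is given in the labels.

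Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM normalization, the filterByExpr filter by group (16369 genes kept, 7693 removed), 1 coefficient per group and all 28 libraries in 1 fit; 12 comparisons were taken as contrasts. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with calls at an adjusted p under 0.05. Fold changes are log2 values. Their standard error was derived from the test, as the absolute log2 fold change over the square root of the F statistic. CPM were computed with the TMM factors. In the comparison of genotypes with vehicle, the mean of VehN and VehD was set against the WT vehicle group, NAVI in 3xTg was set against VehN and DQ against VehD. The vehicles were matched to the drugs by the last letter of their labels. The titles of the WT vehicle libraries say only Veh, and this group was the reference for both drugs in WT. A comparison of a drug effect between genotypes may therefore also hold a difference between vehicles.

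Before the data were examined, 42 gene lists of pathways, cell types and brain regions were fixed; 40 had at least 5 tested members (698 members tested in all). They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 480 tests, and again with an estimated correlation and with fry. The score of a list in a library is the mean over its members of the log2 CPM relative to the mean of all libraries. Which lists the text describes, and the exact permutation test of list scores, were chosen after the list results were seen. An exact permutation test of the CPM of Cdkn2a in 5 comparisons was also chosen after its counts were seen. The effect of a drug on genotype genes was tested by an exact permutation over 70 assignments.

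The genes named were fixed by a rule, also set beforehand. For the genotype difference with vehicle and the effect of each drug in each genotype they are the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 0, or the 5 with the smallest p, as values only, where fewer than 5 genes passed. Up to 4 members with the smallest p come from each list described, and 5 genes with the smallest adjusted p from the interaction and vehicle comparisons. App, Mapt, Thy1, Cdkn1a, Cdkn2a, Gfap, Trem2, Cst7 and C4b are always given. A few genes that the rule also names are not reported here. The 11 genes that differed between NAVI and DQ in WT are named outside that rule.

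Positions come from the RefSeq annotation of the same build, by symbol, for 16303 of the tested genes; GC content and length come from the longest annotated transcript of 16224 genes. The analysis was tested on simulated counts with 200 genes changed by known folds in each comparison. Each gene was drawn independently, without the trends across libraries that many genes share in the real data. For the genotype difference with vehicle 40% of genes changed 1.25-fold, 80% of those changed 1.5-fold and 98% of those changed 2-fold were recovered, and 3.03% of calls were false; for NAVI in 3xTg the shares were 30%, 58% and 86%, with 5.96% of calls false, and for the NAVI effect by genotype 6%, 52% and 82%, with 2.42% false.

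The alternatives were RLE and upper-quartile normalization, DESeq2 1.42.0, limma-voom with quality weights, no low count filter, a filter at a mean of 50 counts, robust estimation, only the libraries of the comparison, the replicate number as a block, 1 surrogate variable (sva 3.50.0), other vehicle references, and each library left out in turn. Added after the data were seen were choroid plexus and thalamus scores as covariates, leaving out 8 libraries with a thalamus score above 0.4 (3xTg NAVI 1, VehN 1 and 2, VehD 1 and 4, WT DQ 1 and 4 and WT vehicle 2), and removing the trend with GC content or transcript length within each library.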

Results

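Messenger RNA was measured by bulk RNA-seq in the hippocampus of female mice of 2 genotypes. The 3xTg-AD line is a mouse model of Alzheimer's disease that carries human amyloid precursor protein (App) and tau (Mapt) transgenes. The wild-type (WT) animals, labelled BL6129, carry neither. Mice received navitoclax (ABT263, here NAVI), an inhibitor of anti-apoptotic BCL-2 proteins, or dasatinib with quercetin (here DQ), or vehicle. There were 7 groups of 4 libraries. They were 3xTg with NAVI, with DQ and with each of 2 vehicles labelled VehN and VehD, and WT with NAVI, with DQ and with vehicle. Libraries held 32080861 to 54019519 counts in 24062 genes, and 16369 genes passed the low count filter.

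The first comparison asked what distinguished the 3xTg hippocampus from WT with vehicle. Read counts on App were 1640 ± 108 CPM (SD, n = 4) in WT with vehicle, 2935 ± 429 (n = 4) in 3xTg VehN and 3235 ± 360 (n = 4) in 3xTg VehD, a log2 difference of 0.91 (SE 0.0784, edgeR adjusted p = 1.73e-08). All 16 3xTg libraries lay between 2410 and 3805 CPM for App and all 12 WT libraries between 1470 and 1800. Thy1, whose promoter cassette drives the transgenes of this line, was 2.86-fold higher (edgeR adjusted p = 9.62e-12). The Mapt difference of 0.13 (SE 0.0486) missed the threshold with edgeR (adjusted p = 0.0714) and passed it with DESeq2 (adjusted p = 0.0452). On the mm10 build, App lies on chromosome 16 from 84952666 to 85175255, Thy1 on chromosome 9 from 44043384 to 44048579 and Mapt on chromosome 11 from 104229409 to 104332090. Whether reads of the human transgenes were counted on the mouse genes is not given in the sources used here, so the levels of App, Mapt and Thy1 may mix both sources to an unknown extent.

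Genes of activated microglia and the chemokine Cxcl13 led the rises in 3xTg. Cst7, a cysteine protease inhibitor of plaque-associated microglia, was 15.1-fold higher (log2 3.91, SE 0.363, edgeR adjusted p = 6.72e-08). Its level was 8.17 ± 1.20 CPM in VehN and 9.31 ± 1.94 in VehD against 0.573 ± 0.119 in WT with vehicle (SD, n = 4 each). The cathepsin Ctse (log2 3.39), Cxcl13 (3.29), the glucan receptor Clec7a (2.80), the inhibitory receptor Lilrb4 (2.06) and the integrin Itgax (1.94) rose as well, as did Myoc (2.30). The peptidase Klk6 rose by 1.97, a call that was lost without WT vehicle replicate 1 (edgeR adjusted p = 0.0558) and without the 8 libraries with a high thalamus marker score (log2 0.96, adjusted p = 0.158). The falls were led by Eno1b (log2 -4.86), Ccl27a (-3.96), Vmn2r29 (-2.61), the GTPase activator Tagap (-2.59), the aldehyde oxidase Aox4 (-2.45), Gm8801 (-2.36), Pcdhga11 (-2.08) and the replication helicase subunit Mcm6 (-2.05). Eno1b, Ccl27a, Vmn2r29, Gm8801 and Pcdhga11 have close copies or shared exons, so their counts are uncertain. Eno1b spanned 0.386 to 18.3 CPM among the WT vehicle libraries and missed the threshold with limma-voom (adjusted p = 0.0882). Gm8801 was at -3.89 without VehD replicate 2, and its call was lost with VehN alone as the 3xTg vehicle (edgeR adjusted p = 0.108).

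In all, 2142 genes passed between 3xTg and WT with vehicle, 930 higher and 1212 lower, of which 249 differed at least 2-fold. The count was 3482 without VehN replicate 1, 1383 without VehD replicate 3, 967 without WT vehicle replicate 1 and 873 without WT vehicle replicate 4.

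**Figure D1:**
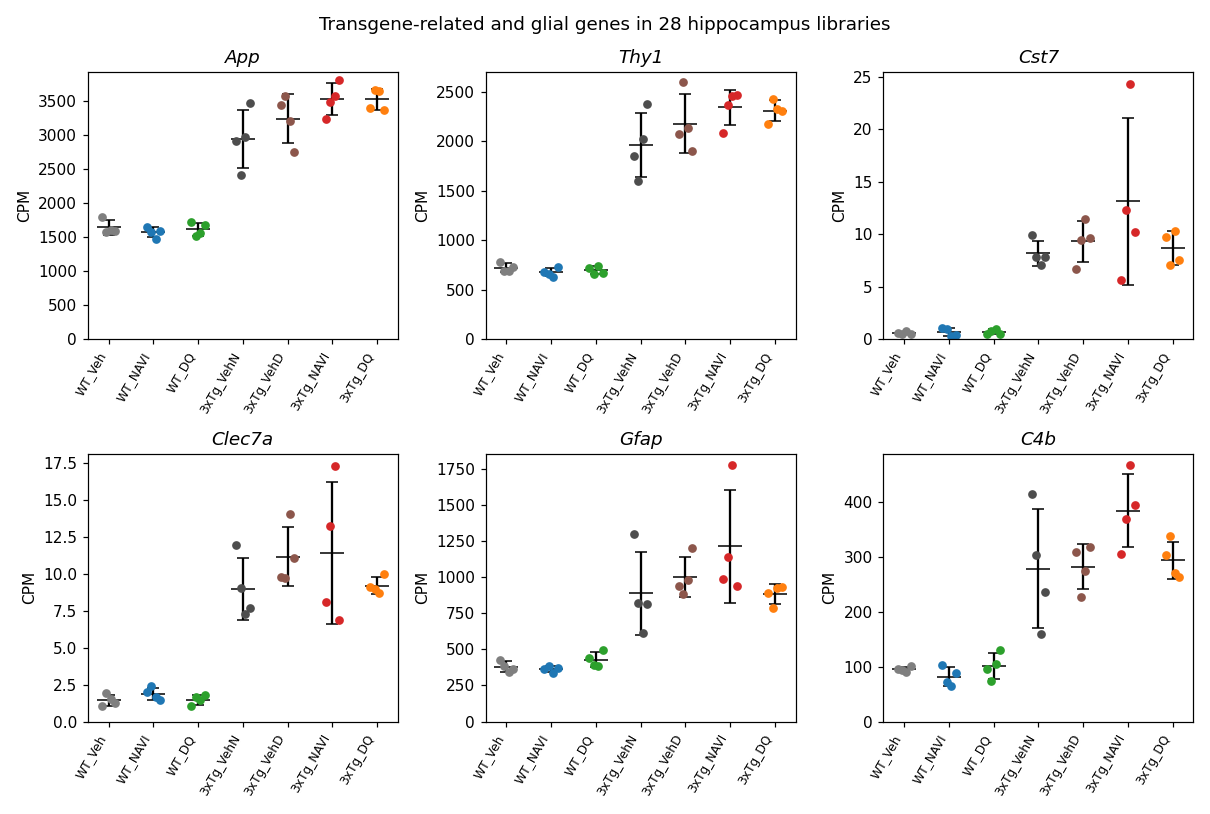
CPM (y axis) of App, Thy1, Cst7, Clec7a, Gfap and C4b in each of the 28 hippocampus libraries, by group (x axis); points are libraries and bars the group mean ± SD (n = 4). App lay at 2410 CPM or above in every 3xTg library and at 1800 or below in every WT library, and Cst7 in 3xTg with NAVI ran from 5.62 to 24.3 CPM.

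Among the fixed gene lists, disease-associated microglia genes changed most broadly in 3xTg. Of 30 tested members 19 rose and none fell, and 23 rose adjusted over the list alone (camera adjusted p = 3.75e-15, but adjusted p = 0.535 with an estimated correlation). Clec7a, Cst7, Cd84 (log2 1.20) and Itgax were its members with the smallest p. Trem2, the lipid receptor of microglia in that list, rose by 0.72 (edgeR adjusted p = 0.0196). That call was lost without WT vehicle replicate 3 (adjusted p = 0.0774), with VehN alone as the 3xTg vehicle (0.0688) and without the 8 high-thalamus libraries (0.0619). Homeostatic microglia markers lay higher as well, with 15 of 16 positive at a median log2 of 0.18 (camera adjusted p = 0.00945, but adjusted p = 0.886 with an estimated correlation). Their score was 0.05 ± 0.12 in VehN and 0.16 ± 0.10 in VehD against -0.11 ± 0.09 in WT with vehicle (SD, n = 4), and the call was lost without WT vehicle replicate 2 (camera adjusted p = 0.0788). Reactive astrocyte genes rose in 12 of 24 and fell in none, with 12 adjusted over the list alone (camera adjusted p = 2.87e-07, but adjusted p = 0.807 with an estimated correlation). They included the intermediate filament Gfap at log2 1.31, the cytokine receptor Osmr at 1.11, the transglutaminase Tgm1 at 2.62 and complement C4b at 1.55. C4b has a near-identical copy and its level is uncertain for that reason. Complement genes rose in 6 of 18 and fell in none, with 7 adjusted over the list alone (camera adjusted p = 4.32e-04, but adjusted p = 0.886 with an estimated correlation). C3ar1 was at 1.01 and C3 at 1.66, the latter lost without the 8 high-thalamus libraries (edgeR adjusted p = 0.0503).

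Interferon-stimulated genes rose in 12 of 28 tested members, among them Mx1 (log2 1.84) and Ifit3 (1.36), while Xaf1, an interferon-induced pro-apoptotic factor, fell by 1.47. Adjusted over the list alone, 18 rose and 1 fell (camera adjusted p = 1.29e-06, but adjusted p = 0.886 with an estimated correlation). Of 32 secretory factors of senescent cells 12 rose and 2 fell, and 14 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00170, but adjusted p = 0.874 with an estimated correlation). The chemokines Ccl3 (2.32) and Ccl4 (2.33) and the growth factor binding protein Igfbp5 (0.42) rose, and Igfbp4 fell by 0.51. Of 15 cell cycle regulators of senescence 1 fell, the cyclin-dependent kinase inhibitor Cdkn2d, by 0.26, and none rose, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.774). The Cdkn2d call was lost without WT vehicle replicate 1 (edgeR adjusted p = 0.106), replicate 3 (0.0679) or replicate 4 (0.0667) and with the GC trend of each library removed (0.246). Cdkn1a (p21) differed by -0.11 (SE 0.188, edgeR adjusted p = 0.705). Cdkn2a (p16) was below the filter, with 0 to 8 counts in any library, and was not tested with edgeR. Its mean was 0.0777 CPM in 3xTg against 0.0628 in WT with vehicle (exact permutation p = 0.632, two-sided, a test chosen after the counts were seen). In an exact permutation test of the mean list score over 495 assignments (two-sided), the disease-associated microglia, reactive astrocyte, interferon and secretory factor lists were higher in 3xTg with an adjusted p of 0.0212 each over 42 tests. No other of the 42 passed. Tests of a drug, or between vehicles, had 70 assignments, and the smallest p these can give (0.0286) came to an adjusted p of 0.1. No such test could pass alone here, so its not passing does not speak against a difference.

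Cholesterol synthesis genes rose in 10 of 22 and fell in 1, with Hmgcs1 (log2 0.42) and Cyp51 (0.41) among them. Adjusted over the list alone, 11 rose and 1 fell (camera adjusted p = 5.77e-04, but adjusted p = 0.886 with an estimated correlation). Lysosomal genes rose in 8 of 30 and fell in 1, the cathepsin Ctss (0.55) among the former. Adjusted over the list alone, 12 rose and 1 fell (camera adjusted p = 7.08e-04, but adjusted p = 0.930 with an estimated correlation). Myelin genes rose in 6 of 14, as many as adjusted over the list alone (camera adjusted p = 0.00170, but adjusted p = 0.930 with an estimated correlation). Among them Trf was at 0.89, and without the 8 high-thalamus libraries at 0.45 (edgeR adjusted p = 0.0789).

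Some neuronal and ribosomal genes fell in 3xTg. Excitatory neuron genes fell in 4 of 12, led by the potassium channel Kcnj4 at log2 -0.74, and 6 fell adjusted over the list alone (camera adjusted p = 0.00427, but adjusted p = 0.886 with an estimated correlation). Synaptic genes fell in 6 of 28, among them the syntaxin Stx1a (-0.67) and the kinase subunit Camk2b (-0.35), and 12 fell adjusted over the list alone (camera adjusted p = 0.00514, but adjusted p = 0.930 with an estimated correlation). The synaptic list was lost with the choroid plexus and thalamus scores as covariates (camera adjusted p = 0.0777). Ribosomal protein genes fell in 12 of 28 and rose in none, with Rpl37 at -0.37, and 20 fell adjusted over the list alone (camera adjusted p = 1.29e-06, but adjusted p = 0.886 with an estimated correlation). In the exact permutation test of list scores none of these 3 lists passed (adjusted p = 0.1 each). With VehD alone as the 3xTg vehicle, Stx1a and Rpl37 missed the threshold (edgeR adjusted p = 0.0929 and 0.0568). Across the 28 libraries the ribosomal protein score followed each library's trend of counts with GC content (Pearson r = 0.940, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 2e-04 over 40 lists). Spearman's rho was 0.947, and r was 0.918 without the 2 farthest libraries and 0.931 within groups. Over all 480 tests of a list in a comparison, 130 passed with the preset correlation, none with an estimated one and 25 with fry. Of 100 assignments of the libraries to groups, 66 gave at least as many list calls, the real one included.

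The genotype difference was tested again within each drug. Disease-associated microglia genes rose in 22 of 30 with NAVI (camera adjusted p = 6.89e-22, but adjusted p = 0.373 with an estimated correlation) and in 12 of 30 with DQ (camera adjusted p = 3.75e-15, but adjusted p = 0.535 with an estimated correlation). Adjusted over the list alone, 27 rose and 1 fell with NAVI, and 15 rose with DQ. With NAVI, 979 genes passed (539 higher and 440 lower in 3xTg), and with DQ 500 passed (275 higher and 225 lower). Of the 2142 genes called with vehicle, 316 were called in the same direction and 3 in the opposite direction with NAVI, where 63.2 would be shared by independent lists. With DQ 326 were called in the same direction and 0 in the opposite one, where 32.3 would be. These comparisons share no libraries. Over the 2142 genes the sign of the difference was the same in 94.2% with DQ and in 55.9% with NAVI, and 157 genes, 94 higher and 63 lower, were called in the same direction in every one of the 3 comparisons.

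The count of genotype genes with NAVI was 1920 without 3xTg NAVI replicate 2, 375 without replicate 3, 592 without replicate 4, 447 without WT NAVI replicate 3 and 579 without WT NAVI replicate 4. With DQ it was 332, 263, 277 and 279 without 3xTg DQ replicates 1, 2, 3 and 4 in that order, and 268 without WT DQ replicate 3.

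**Figure D2:**
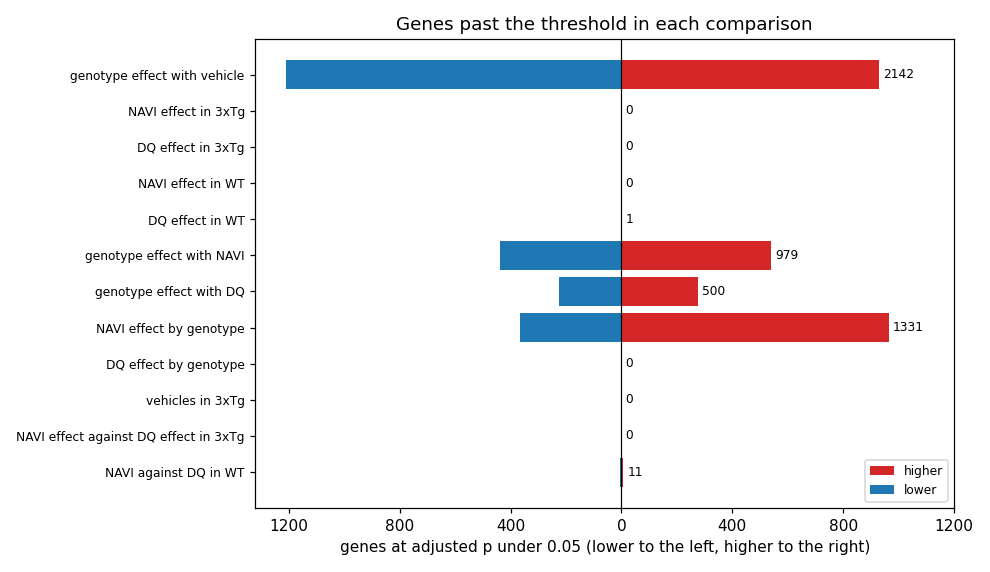
Number of genes at an edgeR adjusted p under 0.05 in each of the 12 comparisons (x axis, genes; higher to the right, lower to the left), fitted on 28 libraries. The bars for the genotype comparisons reach 2142, 979 and 500 genes in both directions together, and that for the NAVI effect by genotype 1331. The comparisons of a drug with vehicle within a genotype hold 0 or 1.

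The effect of NAVI in 3xTg mice was tested against VehN. The genes with the smallest p were the receptor kinase Tyro3 (log2 0.53, SE 0.0997), the actin bundler Fscn1 (0.55, SE 0.109), Rasal1 (0.69, SE 0.142), Prmt2 (0.39, SE 0.0798) and Pianp (0.37, SE 0.0766), all at an edgeR adjusted p of 0.0595. Gfap was at 0.45 (SE 0.176, edgeR adjusted p = 0.105), Trem2 at 0.55 (0.112), Cst7 at 0.68 (0.152) and C4b at 0.46 (0.136). These values moved with single libraries. Without NAVI replicate 3, Gfap was at 0.20, Trem2 at 0.21 and Cst7 at 0.20, and without VehN replicate 1 Gfap was at 0.71 (edgeR adjusted p = 0.0144) and C4b at 0.74 (0.0147). C4b was at 0.28 without VehN replicate 3. No gene passed with edgeR, although 4759 genes lay at an unadjusted p under 0.05, and DESeq2 called 1672 genes and limma-voom 826. Calls also appeared when 1 library was left out, 760 without NAVI replicate 1, 2790 without NAVI replicate 2, 3578 without VehN replicate 1 and 231 without VehN replicate 4. With the mean of both vehicle groups as the reference 1541 genes passed, with the replicate number as a block 2317, with 1 surrogate variable 2829 and without the 8 high-thalamus libraries 2514.

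As lists, excitatory neuron genes (camera adjusted p = 3.41e-04, but adjusted p = 0.883 with an estimated correlation) and synaptic genes (camera adjusted p = 0.00236, but adjusted p = 0.926 with an estimated correlation) lay higher with NAVI in 3xTg. So did ribosomal protein genes (camera adjusted p = 9.12e-06, but adjusted p = 0.886 with an estimated correlation). No member passed over all genes. Adjusted over the list alone 6 of 12, 10 of 28 and 18 of 28 members were higher, and 1 ribosomal member was lower. The synaptic list was lost with the tissue scores as covariates (camera adjusted p = 0.222), and over the 28 libraries the GC trend was followed by the excitatory neuron score (r = 0.606, permutation p = 5.7e-04, but r = 0.464 without the 2 farthest libraries and 0.404 within groups) and more closely by the ribosomal protein score (r = 0.940). The NAVI effect in 3xTg as a whole followed GC content across 16224 genes (Spearman's rho = 0.628), with mean GC slopes of 0.146 with NAVI and -0.126 with VehN (exact permutation p = 0.0857, adjusted p = 0.343). With the GC trend removed the excitatory neuron, synaptic and ribosomal lists still passed (highest camera adjusted p = 0.0128). Immediate early genes such as Junb (log2 1.35, edgeR adjusted p = 0.0595) lay higher as a list (camera adjusted p = 0.00152, but adjusted p = 0.929 with an estimated correlation), with 1 of 24 higher adjusted over the list alone. That call was lost without VehN replicate 1 (camera adjusted p = 0.0549). Interferon-stimulated genes lay lower (camera adjusted p = 2.16e-04, but adjusted p = 0.930 with an estimated correlation), with Rtp4 at -0.73 and Oas2 at -0.78 (edgeR adjusted p = 0.0805 and 0.0909) and none of 28 passing over all genes or adjusted over the list alone.

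The disease-associated microglia list did not pass with NAVI in 3xTg (camera adjusted p = 0.0872, but adjusted p = 0.933 with an estimated correlation), and its adjusted p was 0.883 without NAVI replicate 3, the library with the highest score (0.99 against 0.27, 0.55 and 0.29 in the others). It passed, with higher levels under NAVI, without NAVI replicate 1 (camera adjusted p = 0.0115), NAVI replicate 4 (0.00292) or VehN replicate 1 (0.0144) and with the GC trend removed (0.0363), and it also passed with the tissue scores as covariates. Without NAVI replicate 2, VehN replicate 3 or VehN replicate 4 it lay further from passing (camera adjusted p = 0.216, 0.380 and 0.219), and in the exact permutation test the score difference of 0.17 had a p of 0.457 (adjusted p = 0.533). BCL-2 family genes, which include the proteins navitoclax binds, did not pass as a list (camera adjusted p = 0.728), with Bbc3 at 0.94, Bax at 0.48 and Pmaip1 at -0.65 (edgeR adjusted p = 0.0604, 0.0605 and 0.0946). Neither did the senescence regulators (camera adjusted p = 0.682) nor the secretory factors (camera adjusted p = 0.883). Choroid plexus markers lay lower with NAVI (camera adjusted p = 0.00580, but adjusted p = 0.933 with an estimated correlation), with a mean score of -0.26 ± 2.14 against 1.74 ± 0.53 with VehN (SD, n = 4). That call was lost without NAVI replicate 2 (camera adjusted p = 0.146) and without VehN replicate 1 (0.0622).

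DQ in 3xTg mice was compared with VehD. The smallest p belonged to Gm8773 (log2 -4.78, SE 1.19), Bpifa6 (-4.69, SE 1.22), Depdc1b (-1.07, SE 0.280), the ubiquitin conjugating enzyme Ube2c (-2.05, SE 0.580) and Lzts1 (0.49, SE 0.138), each at an edgeR adjusted p of 0.9999. Gm8773 had 0 CPM in 3 of the DQ libraries, and was at -6.39 without DQ replicate 2, the other one. Bpifa6 ran from 0.0590 to 2.86 CPM with VehD and was at -3.96 without VehD replicate 1, so the size of both differences is uncertain. Gfap differed by -0.18 (SE 0.176), Trem2 by -0.14 (SE 0.220), Cst7 by -0.10 (SE 0.311) and App by 0.12 (SE 0.0869). No gene passed with edgeR, DESeq2 or limma-voom, and 299 genes lay at an unadjusted p under 0.05. In simulated data, where each gene varied independently of the others, the same comparison recovered 70% of genes changed 1.5-fold and 92% of those changed 2-fold. The real libraries also differ by trends that many genes share, so these shares may not hold for them.

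As a list, interferon-stimulated genes lay lower with DQ in 3xTg, with 27 of 28 members negative (camera adjusted p = 3.58e-05, but adjusted p = 0.930 with an estimated correlation). So did disease-associated microglia genes, with 24 of 30 negative (camera adjusted p = 0.00953, but adjusted p = 0.930 with an estimated correlation), and lysosomal genes, with 25 of 30 negative (camera adjusted p = 0.00242, but adjusted p = 0.930 with an estimated correlation). No member of these lists passed over all genes or adjusted over the list alone. Each list was lost without single libraries. The interferon list was lost without DQ replicate 1 (camera adjusted p = 0.872) or VehD replicate 1 (0.0573), and the microglia list without DQ replicate 3 (0.0565) or VehD replicate 4 (0.316). The lysosomal list was lost without DQ replicate 2 (camera adjusted p = 0.0685) or VehD replicate 4 (0.483). The senescence regulators did not pass (camera adjusted p = 0.993), nor did the secretory factors (0.0856), which passed, lower with DQ, without VehD replicate 2 (0.00971). Cdkn2a totalled 5 counts with DQ (0 to 2 in a library), 20 with VehD (3 to 8) and 8 with VehN, at a mean of 0.0278 CPM with DQ against 0.109 with VehD. In an exact permutation test, chosen after the counts were seen, that difference had the smallest p 70 assignments can give (0.0286, two-sided) and did not pass (adjusted p = 0.0714 over 5 comparisons). Thalamus and habenula markers lay lower with DQ as a list (camera adjusted p = 0.0142, but adjusted p = 0.930 with an estimated correlation), a call lost without DQ replicate 4 (0.0800), VehD replicate 1 (0.318) or VehD replicate 4 (0.436).

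Whether a drug moved the genes that distinguish 3xTg from WT was tested on genes called from the other vehicle group, so that no control library was used for both. These genes were called in a separate edgeR fit of that vehicle group and WT vehicle alone, so their number differs from that in the fit of all 28 libraries. For DQ, over 220 genes called between VehN and WT vehicle (118 higher and 102 lower), the mean log2 level signed by the genotype difference was 0.63 ± 0.07 with drug and 0.74 ± 0.07 with vehicle (SD, n = 4). The change of -0.11 had an exact permutation p of 0.0857 (two-sided, 70 assignments, smallest possible 0.0286), and 79.5% of genes moved against the genotype difference. For NAVI, over 242 genes called between VehD and WT vehicle (137 higher and 105 lower), the change was -0.04 (exact permutation p = 0.4, two-sided), with 57.9% of genes against the genotype difference. Leaving out NAVI replicates 1, 2, 3 and 4 gave -0.0145, -0.0688, -0.0762 and -0.0190, and leaving out single libraries gave -0.145 to -0.0827 for DQ.

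In WT mice NAVI was compared with vehicle. D630041G03Rik (log2 -0.83, SE 0.154), the sialyltransferase St3gal1 (-0.46, SE 0.0938), the glutathione-degrading enzyme Chac1 (-0.96, SE 0.216), Capn11 (3.44, SE 0.787) and the stress transcription factor Atf5 (-0.61, SE 0.146) had the smallest p, with edgeR adjusted p from 0.238 to 0.614. Capn11 rested on WT NAVI replicate 3, at 4.66 CPM against 0.203 to 0.428 in the other 3, and was at 1.37 without it. No gene passed with edgeR, 1267 lay at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 3. The count was 1 without WT NAVI replicate 3, WT vehicle replicate 3 or WT vehicle replicate 4.

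With DQ in WT 1 gene differed, Cthrc1, a secreted protein with a collagen repeat, at a log2 difference of -1.91 (SE 0.238, edgeR adjusted p = 3.76e-04). Its level was 0.775 ± 0.0717 CPM with DQ and 2.92 ± 0.648 with vehicle (SD, n = 4). The gene missed the threshold with limma-voom (adjusted p = 0.166) and with edgeR on the libraries of that comparison alone (0.0503). Polr2k (log2 -0.52), Mtmr12 (-0.30), Pkdrej (-0.79) and Cd79b (-3.97) followed Cthrc1 in p, at edgeR adjusted p from 0.290 to 0.605. All of these but Cd79b lie on chromosome 15. Cd79b rested on WT vehicle replicate 1, at 8.59 CPM against 0.232 to 0.262 in the other 3, and was at -0.75 without it. Cdkn2a totalled 3 counts with DQ and 10 with vehicle (exact permutation p = 0.0286, adjusted p = 0.0714). DESeq2 called 4 genes and limma-voom 0, and 554 lay at an unadjusted p under 0.05. With edgeR 5 passed without WT DQ replicate 1, 2 without WT vehicle replicate 1 and 2 without WT vehicle replicate 3.

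As lists, immediate early genes lay higher in WT with NAVI, with 22 of 24 members positive (camera adjusted p = 3.24e-06, but adjusted p = 0.874 with an estimated correlation), Arc at log2 0.76 and Fos at 0.94. With DQ 23 of 24 were positive (camera adjusted p = 5.51e-07, but adjusted p = 0.872 with an estimated correlation), with Arc at 0.64 and Fos at 0.77. Without WT DQ replicate 3 these were 0.36 and 0.43, and without WT vehicle replicate 1 Arc was at 0.98. Antigen presentation genes lay lower with NAVI, with 18 of 19 negative (camera adjusted p = 3.11e-05, but adjusted p = 0.886 with an estimated correlation) and H2-K1 at -0.59. With DQ 18 of 19 were negative (camera adjusted p = 1.40e-05, but adjusted p = 0.886 with an estimated correlation), with H2-K1 at -0.46 and B2m at -0.44. No member of either list passed over all genes or adjusted over the list alone. Both drugs were compared with the same 4 WT vehicle libraries, so that these values are not independent of each other. The antigen presentation score spanned -0.66 to 0.44 in those 4 libraries, and in the exact permutation test it did not pass with NAVI (p = 0.257, adjusted p = 0.372) or with DQ (p = 0.371, adjusted p = 0.473). The T and B cell score was -0.39 with NAVI and -0.37 with DQ against 0.01 ± 0.80 with vehicle (SD, n = 4), where WT vehicle replicate 1 was at 1.18. The BCL-2 family did not pass with NAVI (camera adjusted p = 0.987).

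NAVI and DQ were compared directly in WT, and 11 genes differed, 7 higher and 4 lower with NAVI. They were chosen for naming after their values were seen. Cthrc1 (chromosome 15, 39076932 to 39087121) was 5.91-fold higher with NAVI (log2 2.56, SE 0.237, edgeR adjusted p = 1.03e-06), at 4.60 ± 1.03 CPM against 0.775 ± 0.0717 with DQ (SD, n = 4). Mtmr12 (0.51), Polr2k (0.67), Baalc (0.34), Nudcd1 (0.50), Rpl3 (0.30) and Pkdrej (0.94) were higher, and Erich5 (-1.53), Jrk (-0.56), Card10 (-1.14) and Poldip3 (-0.30) lower. All 11 lie on chromosome 15, between 12204970 and 85821733 on mm10, where 3.88% of tested genes with a position lie on the whole chromosome (one-sided Fisher's exact p = 2.78e-16). That test treats genes measured in the same libraries as independent, and the chromosome was chosen after the calls were seen. Its p therefore does not measure the spread between libraries. WT with vehicle lay between the drugs for Cthrc1, at 2.92 ± 0.648 CPM, and for Erich5, at 6.21 ± 0.442 against 3.31 ± 1.75 with NAVI and 9.57 ± 1.11 with DQ (SD, n = 4 each). Mtmr12 was at 64.6 ± 3.72 CPM with vehicle, 74.8 ± 5.54 with NAVI and 52.7 ± 3.77 with DQ. DESeq2 called 38 genes and limma-voom 39.

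Of the 11 genes, Cthrc1, Mtmr12, Erich5, Polr2k and Jrk passed without each of the 8 WT libraries of this comparison in turn, and each of the others was lost without at least 5 of them. The count was 5 without WT DQ replicate 1, 20 without replicate 2, 7 without replicate 3, 7 without replicate 4 and 5 without WT NAVI replicate 2. It was 1, Cthrc1, with edgeR on the libraries of this comparison alone and without the 8 high-thalamus libraries, while the median signed difference of the 11 genes was 0.564 and 0.518 in these fits, against 0.558, and all 11 kept their direction.

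**Figure D3:**
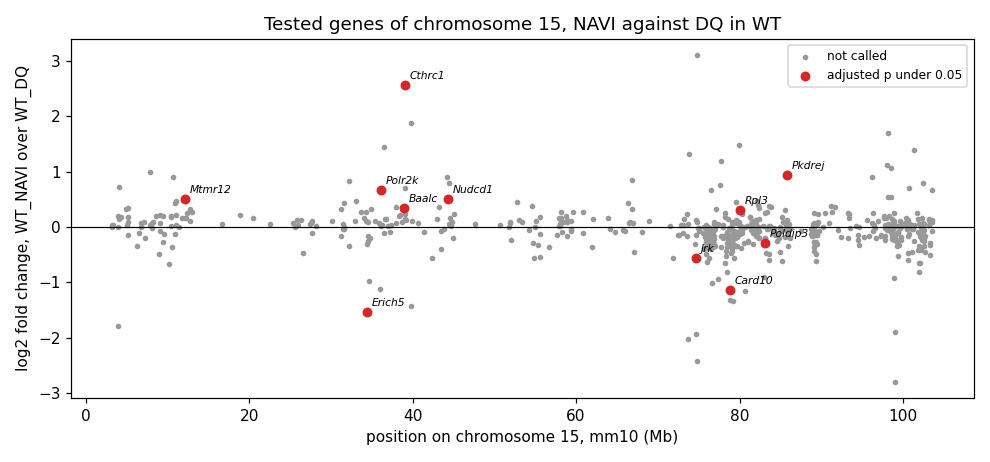
Log2 fold change of WT NAVI over WT DQ (y axis, n = 4 each) for tested genes along chromosome 15 (x axis, position in Mb on mm10); red points are genes at an edgeR adjusted p under 0.05. The 11 red points lie between 12.2 and 85.8 Mb, with Cthrc1 at 2.56 and Erich5 at -1.53.

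The NAVI effect was compared between genotypes. Pianp (log2 0.59), Chac1 (1.55), Crip2 (1.04) and the tau kinase Mark2 (0.51) had a higher effect in 3xTg than in WT and the mitotic kinase Wee1 (-0.59) a lower one, each at an edgeR adjusted p of 0.0427, the smallest of all genes. In all 1331 genes passed, 964 with a higher effect in 3xTg and 367 with a lower one. Ribosomal protein genes had a higher effect in 3xTg in 13 of 28 members and a lower one in none, and 18 and 2 adjusted over the list alone (camera adjusted p = 8.38e-06, but adjusted p = 0.886 with an estimated correlation). Excitatory neuron genes had a higher effect in 3 of 12, Kcnj4 (1.06) among them, and 6 adjusted over the list alone (camera adjusted p = 0.00423, but adjusted p = 0.886 with an estimated correlation). Of 19 antigen presentation genes 1 was higher, H2-DMa (0.60), as adjusted over the list alone (camera adjusted p = 0.01002, but adjusted p = 0.930 with an estimated correlation). With the GC trend of each library removed no gene passed, and the excitatory neuron and antigen presentation lists were lost (camera adjusted p = 0.143 and 0.0741).

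Over the 1331 genes, which were chosen with all libraries, the median signed difference was 0.473 or more with each library left out in turn, against 0.533. The count of 1331 rested on single libraries. It was 0 without 3xTg NAVI replicates 3 or 4, VehN replicates 2 or 3, WT NAVI replicates 2 or 4 or WT vehicle replicate 1, and 1 without WT NAVI replicate 3 or WT vehicle replicate 4. In each of these cases Pianp, Chac1, Wee1, Crip2 and Mark2 were lost, at edgeR adjusted p from 0.0564 to 0.125. It was 3615, 4214 and 2799 without 3xTg NAVI replicate 2, VehN replicate 1 and WT vehicle replicate 2, and without the last the antigen presentation list was lost (camera adjusted p = 0.0626). The DQ effect differed between genotypes for no gene with edgeR, with 467 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Cthrc1 came first (log2 1.67, SE 0.315, edgeR adjusted p = 0.265).

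**Figure D4:**
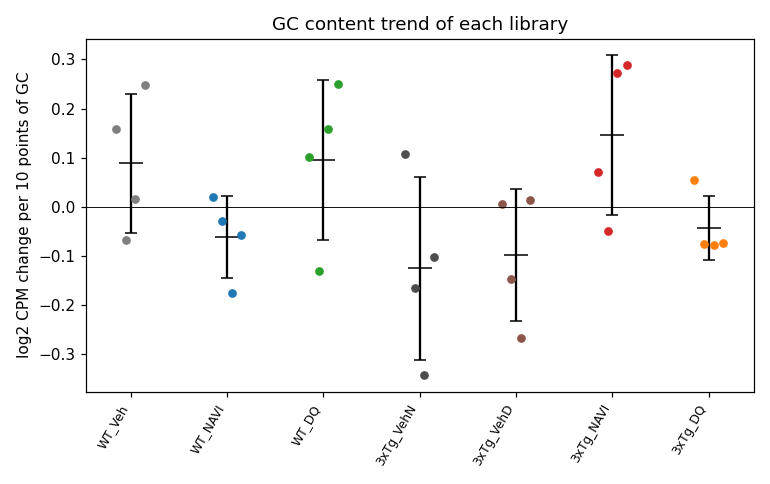
Trend of counts with GC content in each of the 28 libraries (y axis, log2 CPM change per 10 points of GC, relative to the mean of all libraries) by group (x axis); points are libraries and bars the mean ± SD (n = 4). Group means ran from -0.126 in 3xTg VehN to 0.146 in 3xTg NAVI, and none of 8 comparisons of groups passed an exact permutation test (smallest adjusted p = 0.343). The smallest p that 70 assignments can give, 0.0286, could not pass alone over 8 comparisons.

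The vehicles were compared in 3xTg. Extracellular matrix genes lay higher in VehN than in VehD as a list, with 22 of 22 members positive and 4 higher adjusted over the list alone (camera adjusted p = 8.59e-13, but adjusted p = 0.535 with an estimated correlation). So did glucocorticoid-responsive genes, with 18 of 18 positive and 7 higher adjusted over the list alone (camera adjusted p = 2.01e-12, but adjusted p = 0.373 with an estimated correlation). Nid1 was at log2 0.91, Tsc22d3 at 0.46 and Pdk4 at 0.65, and none of them passed. Leptomeningeal fibroblast markers, 13 of 13 positive (camera adjusted p = 3.03e-09, but adjusted p = 0.872 with an estimated correlation), and choroid plexus markers, 14 of 14 positive (camera adjusted p = 8.95e-07, but adjusted p = 0.925 with an estimated correlation), also lay higher. The choroid plexus score was 1.74 ± 0.53 in VehN and -0.34 ± 2.52 in VehD (SD, n = 4). Tmem252 (log2 2.12), BC018473 (2.35), Inhba (-0.87), Vps13c (-0.37) and the ceramidase Acer2 (1.03) had the smallest edgeR adjusted p, 0.58 each. Tmem252 was at 1.47 and BC018473 at 1.65 without VehN replicate 2, which held 5.90 and 3.43 CPM against highest levels of 2.75 and 1.17 in the other VehN libraries. No gene passed with edgeR (1 without VehN replicate 1), 807 lay at an unadjusted p under 0.05, DESeq2 called Tmem252 and BC018473, and limma-voom called 0. The NAVI effect in 3xTg differed from the DQ effect in 3xTg for no gene with edgeR, DESeq2 or limma-voom, with 666 at an unadjusted p under 0.05.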

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

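The tests of the chromosome 15 genes and the tests of the GC trend in genes that differed between genotypes were chosen only after the results were seen, and the splits for the NAVI effect by genotype were drawn in a larger number after a first draw gave a share of 0.05. The GC tests for genes that kept or lost their call with that trend removed replaced earlier ones whose values had been seen.

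Single libraries lay apart from the other 3 of their group in 5 of 98 groups of values, where chance gives about 5%. Mapt was at 546.9 CPM in WT NAVI replicate 3, against 602.1 to 612.3 in the others. Total counts per 1e+06 were 52.32 in 3xTg VehN replicate 3, against 41.79 to 43.4. The choroid plexus score was 1.655 in WT NAVI replicate 2, against -1.623 to -1.269. The thalamus and habenula score was 0.4963 in WT vehicle replicate 2, against -0.3904 to -0.2691. The GC slope was 0.054 in 3xTg DQ replicate 1, against -0.07779 to -0.07431.

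The NAVI effect differed between genotypes by a test of the difference itself for 1331 genes, with the smallest adjusted p for Pianp (log2 0.5898), Chac1 (1.552), Wee1 (-0.5941), Crip2 (1.044) and Mark2 (0.508), and for the ribosomal protein (camera adjusted p = 8.381e-06, but adjusted p = 0.886 with an estimated correlation), excitatory neuron (0.004231, but adjusted p = 0.886 with an estimated correlation) and antigen presentation lists (0.01002, but adjusted p = 0.930 with an estimated correlation). Of 100 splits of the libraries 3 gave as many genes, the real one included, with a highest other count of 2286, but so did 3 of the first 60, a share of 0.05 that meets the rule for chance, so chance cannot be firmly excluded. Choroid plexus or thalamic tissue is argued against as the whole cause, since with both scores as covariates the genes' median signed difference was 0.550, against 0.533 without. The lowest median without 1 library was 0.473, but the genes were chosen with all libraries, so it cannot decide on a single library as the cause. The count fell to 0 in 7 such cases. A GC content trend that differs between libraries may account for much of the difference in effect: with that trend removed the median fell to 0.210 and its median SE from 0.150 to 0.0944, and none of the 1331 genes passed. The correction can also remove biology that goes with GC content, so a genotype difference in the response to NAVI stays open.

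The 11 genes that differed between NAVI and DQ in WT all lie on chromosome 15. Of 35 splits of the 8 libraries only the real one gave as many, with a highest other count of 8. The share of the real split is the smallest this design can give and is not adjusted over the 13 counts tested so. Chance can therefore not be firmly excluded for this count. A drug difference shared by both genotypes is argued against. In 3xTg, with NAVI taken against VehN and DQ against VehD, the same genes differed by a mean of -0.127 in the WT direction, against 0.849 in WT. The 95% interval of -0.217 to -0.0367 was taken across the 11 genes, so it does not measure the spread between libraries. Choroid plexus or thalamic tissue is argued against too, since 3.4% of the 500 genes that follow the choroid plexus and thalamus scores most closely lie on that chromosome. All 11 kept their direction with these scores as covariates, at a median of 0.541 against 0.558, although 5 of 11 calls were left. A chromosome 15 haplotype that differs between WT animals is a candidate explanation: 19.5% of the 379 genes of that region not called lay at an unadjusted p under 0.05, against a median of 9.24% and a maximum of 14.5% in windows elsewhere. No genotypes of the animals were used here, and an effect of the drugs in WT alone stays open.

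Between 3xTg and WT with vehicle 2142 genes differed, and of 100 splits only the real one gave as many (highest other 361). The share of the real split is not adjusted over all the counts tested so, and chance can therefore not be firmly excluded by it. Haplotype blocks between the lines in which most genes change are argued against as the whole cause. Of the called genes' next tested genes 16.9% were called too, 3.76 points above the mean of random sets (highest 15.3%). Blocks that change only scattered genes would raise this share little, so the test cannot decide on them, and they stay open. Choroid plexus or thalamic tissue is argued against as the whole cause, with a median signed difference of 0.344 with both scores as covariates, against 0.343 without. Other tissue was not tested as a cause. A GC content trend is argued against as the whole cause. With it removed, the separate animals given NAVI differed the same way, by a median of 0.198, narrowly above the bound set, over the 1165 genes still called after that correction. Over the other 977 the median was 0.118. The mean signed score of a library differed by 0.409 and 0.160 over these sets (exact permutation p = 0.0286 each, the smallest 70 assignments can give). Of the 319 genes also called with NAVI, where the GC trend of the genotypes is opposite, 99.1% kept their direction, but these were selected by passing in both comparisons. Before the correction 55.9% of all 2142 genes kept it, 66.6% of the 1165 and 43.2% of the 977. After removal of the GC trend 78.7% of the 1165 and 82.4% of the 977 did. That trend may account for part of the size: with it removed the median went from 0.424 (median SE 0.105) to 0.362 (0.0877) over the 1165 and from 0.284 (0.0817) to 0.130 (0.0648) over the 977, whose calls ended because the difference shrank, and with NAVI before the correction the medians were 0.138 and -0.0302. The genotype itself stays among the open explanations for all of these genes.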

How the results depend on the processing

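The choroid plexus and thalamus covariates, the removal of the GC or length trend, the exclusion of 8 libraries with a high thalamus score and the exact test of list scores were chosen only after the results were seen. Of 7454 values of named genes and lists, the homeostatic microglia list apart, under all alternatives, 6717 kept their side of the threshold and, where past it, their direction, 417 lost the threshold, 318 gained it and 2 reversed. The heat shock list with DQ in WT (camera adjusted p = 0.00305, but adjusted p = 0.925 with an estimated correlation) ranged from 1.84e-05 without WT_Veh replicate 3 to 0.970, with its direction reversed, without WT_Veh replicate 4, and the choroid plexus list between vehicles reversed with choroid plexus and thalamus scores as covariates (0.851), by the construction of that fit. Among named genes past the threshold in neither setting the sign changed 42 times. The filter of a mean of 50 counts left 13815 genes and no low count filter 21041. Cdkn2a, with 0 to 8 counts, was not tested with edgeR. Libraries of the same replicate number correlated by -0.400 to 0.463 (mean 0.0301, against -0.01005 for other numbers), and 10 of 28 correlated best with their own number. These values show no strong pairing by number, but they cannot exclude that a number marks a shared batch or day. For the counts below that moved by over 1.5 times, the cause was not tested.

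The genotype effect with vehicle (2142 genes) was 1118 with only the libraries of the contrast, 3283 with a replicate block, 623 with only 3xTg_VehD as vehicle and 5033 without the libraries with a high thalamus score, and 873 (without WT_Veh replicate 4) to 3482 (without 3xTg_VehN replicate 1) when 1 library was left out. The NAVI effect in 3xTg (0) was 1672 with DESeq2, 826 with limma-voom, 2317 with a replicate block, 2829 with 1 surrogate variable, 1541 with the mean of both 3xTg vehicle groups and 2514 without the libraries with a high thalamus score, and 0 (without 3xTg_NAVI replicate 3) to 3578 (without 3xTg_VehN replicate 1). The DQ effect in 3xTg was 0 under every alternative run and without each library. The NAVI effect in WT (0) was 3 with DESeq2 and 3 with limma-voom, and 0 (without WT_NAVI replicate 1) to 1 (without WT_NAVI replicate 3). The DQ effect in WT (1) was 4 with DESeq2, 0 with limma-voom, 0 with only the libraries of the contrast and 3 with the GC content trend removed, and 1 (without WT_DQ replicate 2) to 5 (without WT_DQ replicate 1).

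The genotype effect with NAVI (979) was 1641 with DESeq2, 1603 with limma-voom, 535 with only the libraries of the contrast and 1884 with a replicate block, and 375 (without 3xTg_NAVI replicate 3) to 1920 (without 3xTg_NAVI replicate 2). The genotype effect with DQ (500) was 1545 with limma-voom and 157 without the libraries with a high thalamus score, and 263 (without 3xTg_DQ replicate 2) to 632 (without WT_DQ replicate 2). The NAVI effect by genotype (1331) was 2544 with DESeq2, 2007 with limma-voom, 0 with no low count filter, 0 with only the libraries of the contrast, 3315 with a replicate block, 3632 with 1 surrogate variable, 3169 with choroid plexus and thalamus scores as covariates, 4925 without the libraries with a high thalamus score and 0 with the GC content trend removed, and 0 (without 3xTg_NAVI replicate 3) to 4214 (without 3xTg_VehN replicate 1). The DQ effect by genotype (0) was 1 with DESeq2, 1 with 1 surrogate variable and 1 with choroid plexus and thalamus scores as covariates, and 0 without each library. The vehicles in 3xTg (0) gave 2 with DESeq2, and 0 to 1 (without 3xTg_VehN replicate 1). The NAVI effect against DQ effect in 3xTg was 0 throughout. NAVI against DQ in WT (11) was 38 with DESeq2, 39 with limma-voom, 1 with only the libraries of the contrast and 1 without the libraries with a high thalamus score, and 5 (without WT_DQ replicate 1) to 20 (without WT_DQ replicate 2). The gene list tests (130) were 0 with an estimated correlation and 25 with fry, and 124 (without 3xTg_DQ replicate 1) to 145 (without WT_Veh replicate 4).

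The drug effect on genotype genes stayed negative and did not pass in any setting. For NAVI it was -0.0762 to -0.0145 without 1 library, and for DQ -0.145 to -0.0827.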

Other observations

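The tests of list scores against the GC trend and of the first principal component were chosen only after the data were seen.

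In the genotype difference with NAVI, cholesterol synthesis genes rose in 9 of 22 (camera adjusted p = 3.62e-08, but adjusted p = 0.807 with an estimated correlation) and lysosomal genes in 10 of 30 (camera adjusted p = 2.69e-06, but adjusted p = 0.886 with an estimated correlation). With DQ, cholesterol synthesis genes rose in 4 of 22 (camera adjusted p = 6.83e-07, but adjusted p = 0.872 with an estimated correlation). In WT, leptomeningeal fibroblast markers such as Slc22a6 (log2 1.19, and 0.77 without WT_DQ replicate 3) and Col1a2 (0.79) lay higher with DQ than with vehicle as a list, and none passed (camera adjusted p = 4.17e-05, but adjusted p = 0.926 with an estimated correlation).

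Choroid plexus content varied widely between libraries, and Ttr, its most abundant secreted transcript, ran from 27.9 to 5366 CPM. The first principal component of 1000 genes held 27.1% of the variance and followed the choroid plexus score (Pearson r = 0.948, Spearman rho = 0.893, permutation p = 1e-05, the smallest the permutations can give, r = 0.941 without the 2 farthest libraries). It followed the thalamus and habenula score less closely (r = 0.767, rho = 0.661, r = 0.685 without the 2 farthest libraries). The score of nuclear respiratory chain genes followed the GC trend of the 28 libraries (r = 0.879, rho = 0.842, permutation adjusted p = 2e-04, r = 0.845 without the 2 farthest libraries).

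Other splits of the same libraries gave far fewer genes than the real one for the genotype effect with NAVI and with DQ. With NAVI only 1 of 35, the real one, gave as many as 979 genes (highest other 1). With DQ 1 of 35, again the real one, gave as many as 500 (highest other 2). That share is the smallest 35 splits can give and is not adjusted over all the counts tested so. Chance can therefore not be firmly excluded for either count. Chance could not be excluded for the NAVI effect in 3xTg, where 3 of 35 splits gave as many as 4759 genes at an unadjusted p under 0.05 (highest other 7155), or for the NAVI effect in WT, with 5 of 35 (1267, highest other 2415). The same holds for the DQ effect in 3xTg, with 22 of 35 (299, highest other 1651), the DQ effect in WT, with 12 of 35 (1 call, highest other 15), and the DQ effect by genotype, with 62 of 100 (467, highest other 3402). It also holds for the vehicles in 3xTg, with 14 of 35 (807, highest other 5230), for the NAVI effect against the DQ effect in 3xTg, with 37 of 100 (666, highest other 5971), and for the gene list tests, with 66 of 100 (130 list calls, highest other 222). Single splits gave several times the real count, although the median of the other splits was 356 for the DQ effect in 3xTg and 431 for the vehicles. Such splits may point to a structure of the libraries other than their groups, which was not tested.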
